A study of Mus musculus with 10 samples.

How the data were processed

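The deposited files hold raw counts per gene, which per the submitters' processing notes came from reads aligned with STAR 2.7.5c to the mouse genome build GRCm38. Per the labels' protocols, RNA was taken from ribosomes pulled down with antibodies against GFP 4 weeks after injection of 400 nl of virus per side at 0.1 µl per minute, and libraries were made from amplified cDNA. The way reads were assigned to genes, the strand setting, the annotation release and the trimming are not given in the sources used here. The libraries are unstranded in design, so reads on overlapping genes cannot be assigned to 1 of them, and members of gene families with near-identical sequence can share or lose reads. The libraries were amplified by PCR without molecular identifiers, and read numbers are given without an error. Amplification makes low counts more variable than their size implies. The labels do not say whether replicates are separate animals, so the p-values measure the spread between these samples.

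The table had 55536 gene identifiers, of which 55450 were matched to a symbol in GENCODE M21 (GRCm38), which also gave the coordinates. The 86 without a symbol held at most 0.0191% of the counts of a library. Genes were kept when they passed edgeR's filter for expression by group, and the IL-17 receptor genes were kept in any case, which left 20301 genes and removed 35235. Counts were scaled by TMM and tested with edgeR 4.0.16 by its quasi-likelihood F test in R 4.3.3, with all 10 libraries in 1 model and Benjamini-Hochberg adjustment at 0.05 within each comparison. CPM values are TMM-scaled, errors beside them are standard deviations and errors beside log2 fold changes are standard errors. The common dispersion was 0.239, a biological coefficient of variation of 0.489.

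The 44 gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01 between members, adjusted over lists within a comparison, and again with the correlation estimated from the data. A list needed at least 3 tested members. Counts of members adjusted over the list alone use the same p-values with the adjustment run over that list. Genes named singly in a comparison were the 8 per direction with the largest fold among those past the threshold, with an average log2 CPM of at least 3 and no overlap between groups, leaving out predicted and unnamed genes. To these were added the receptor genes, Rpl10a, up to 4 members with the smallest p of each called list and up to 2 members with the highest CPM of each of the 23 cell type lists.

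The groups, the lists, the test and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors or upper quartile scaling in edgeR, no filter or a filter at 1 CPM in 3 libraries, a model of only the 2 groups compared, replicate numbers as blocks, the estimated correlation, and each library left out in turn. Added after the results were seen were the fits without Il17ra-Cre replicates 1 and 2 together and without Il17rc-Cre replicates 1 and 3 together, and the rotation test fry. The first of these fits leaves 1 Il17ra-Cre library, so for comparisons with that group only its effect sizes and directions are read. Its numbers of genes are listed only where the dependence on the processing is described, and no conclusion is drawn from them. In simulated data with 100 genes changed by each fold among the 20301, the test recovered 44% of 4-fold changes for Il17rb-Cre against Il17ra-Cre, 60% for Il17rb-Cre against Il17rc-Cre and 37% for Il17ra-Cre against Il17rc-Cre. Of 2-fold changes it recovered 0%, 6% and 5%. Far more genes differed in the real comparisons with Il17rb-Cre, where the adjustment is less strict, so these shares do not give the recovery there. Small differences that did not pass remain undecided.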

Results

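Ribosome-bound RNA was profiled from mouse primary somatosensory cortex by translating ribosome affinity purification (TRAP). In this method a Cre-dependent virus adds a GFP tag to the large-subunit ribosomal protein L10a, and an antibody against GFP then pulls down ribosomes of the cells that carry Cre. Cre was driven from the gene of 1 of 3 interleukin-17 (IL-17) receptor subunits, Il17ra, Il17rb or Il17rc. The series asks which genes are translated in the cells marked by each driver. Of 10 libraries, 3 were labelled Il17ra-Cre, 3 Il17rb-Cre and 4 Il17rc-Cre. Total counts were 42642810, 39692925 and 165844244 in the Il17ra-Cre replicates 1 to 3. They were 55007935, 78794795 and 71867914 in the Il17rb-Cre replicates 1 to 3 and 44669145, 68660776, 70995932 and 65290022 in the Il17rc-Cre replicates 1 to 4. Between 21205 and 24790 genes had at least 1 count in a library. Libraries of whole-tissue RNA were not analysed here, so levels were compared between pull-downs and not with the surrounding tissue.

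The transcripts of the driver receptors were examined first, as a check of the labels. Il17rc followed its label against Il17rb-Cre but not against Il17ra-Cre, and neither Il17ra nor Il17rb was higher in the libraries labelled with its own driver. Il17rc (ENSMUSG00000030281, GRCm38 chromosome 6, 113471427 to 113483140), a receptor subunit that pairs with Il17ra, was at 28.3 ± 8.37 CPM (counts scaled to library size; mean ± SD, n = 4) in libraries labelled Il17rc-Cre and at 29.4 ± 10.4 CPM (n = 3) in those labelled Il17ra-Cre. It was at 1.89 ± 1.15 CPM (n = 3) in libraries labelled Il17rb-Cre, a log2 fold change of -3.90 ± 0.46 (SE) against Il17rc-Cre (edgeR adjusted p = 1.4e-04) and -3.96 ± 0.47 against Il17ra-Cre (edgeR adjusted p = 1.71e-04). Il17ra (ENSMUSG00000002897, chromosome 6, 120463247 to 120487559), the subunit shared by several IL-17 receptor complexes, was at 18.5 ± 2.53, 26.5 ± 7.31 and 18.8 ± 2.97 CPM in libraries labelled Il17ra-Cre, Il17rb-Cre and Il17rc-Cre. None of its 3 comparisons passed the test (edgeR adjusted p = 0.113, 0.102 and 0.982). Without Il17rb-Cre replicate 1 the log2 fold changes of 0.74 and 0.66 for Il17rb-Cre against Il17ra-Cre and Il17rc-Cre passed it (edgeR adjusted p = 0.0263 and 0.0341).

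Il17rb (ENSMUSG00000015966, chromosome 14, 29996135 to 30008896), the subunit that binds IL-17E, was at 0.714 ± 0.138 CPM in libraries labelled Il17rb-Cre, 2.26 ± 1.31 CPM in those labelled Il17ra-Cre and 1.26 ± 1.13 CPM in those labelled Il17rc-Cre. Its raw counts were 35, 46 and 61 in the Il17rb-Cre replicates and 65, 48 and 640 in the Il17ra-Cre replicates, so it was measured on few reads. The log2 fold change of -1.66 ± 0.95 for Il17rb-Cre against Il17ra-Cre did not pass the test (edgeR adjusted p = 0.188). Without Il17rc-Cre replicates 1 and 3, left out after the data were seen, the same value passed it (edgeR adjusted p = 0.0423). About 3.8% of its exonic length overlaps the neighbouring gene Actr8, whose reads could not be told apart without strand. Il17rd and Il17re were below 1 CPM on average in each group and passed in none of the comparisons. Without Il17rc-Cre replicate 4, Il17rd passed for Il17rb-Cre against Il17rc-Cre (log2 fold change -3.88, edgeR adjusted p = 0.0388). Because the Il17rb transcript was not higher in the libraries labelled with its own driver, the directions given for all groups rest on the labels as deposited.

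Rpl10a (chromosome 17, 28328471 to 28331033), the mouse gene for the tagged protein, was at 669.6, 602.4 and 665.1 CPM in the Il17rb-Cre replicates and at 267.1, 190.8, 266.4 and 228.0 CPM in the Il17rc-Cre replicates. In libraries labelled Il17ra-Cre it was at 58.7 and 70.9 CPM in replicates 1 and 2 and at 678.8 CPM in replicate 3. Whether reads of the viral construct fall on this gene is not stated in the sources used here. All 10 libraries share 1 estimate of the spread of a gene in the model, so the uneven Il17ra-Cre replicates enter the error of each comparison. The log2 fold changes of 1.26 ± 0.76 for Il17rb-Cre against Il17ra-Cre and 1.44 ± 0.70 for Il17rb-Cre against Il17rc-Cre did not pass the test (edgeR adjusted p = 0.211 and 0.126). Without Il17ra-Cre replicate 3 they were 3.32 and 1.44 and passed it (edgeR adjusted p = 4.32e-06 and 5.13e-05), and for Il17ra-Cre against Il17rc-Cre the value turned from 0.18 to -1.88 (edgeR adjusted p = 7.01e-04). With replicate 3 as the 1 Il17ra-Cre library left, the value for Il17rb-Cre against Il17ra-Cre was -0.059.

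**Figure D1:**
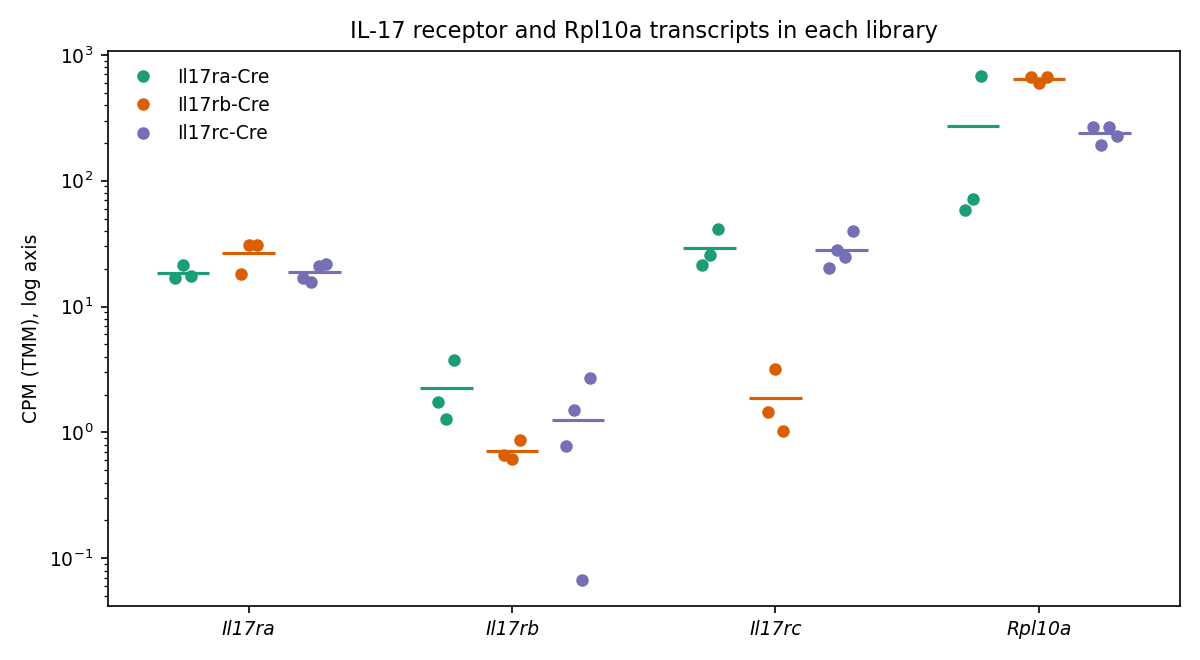
CPM (TMM-scaled, log axis) of Il17ra, Il17rb, Il17rc and Rpl10a, with 1 point per library and a bar at the group mean, for libraries labelled Il17ra-Cre (3), Il17rb-Cre (3) and Il17rc-Cre (4). Il17rc lies between 1.03 and 3.19 CPM in the Il17rb-Cre libraries and between 20.3 and 41.2 CPM in the others, and Rpl10a is at 58.7, 70.9 and 678.8 CPM in the Il17ra-Cre libraries.

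Libraries labelled Il17rb-Cre had higher excitatory and pan-neuronal markers and lower astrocyte, oligodendrocyte and microglial markers than libraries labelled Il17ra-Cre. These list calls were lost with an estimated correlation (adjusted p between 0.278 and 0.416). Sst, the peptide somatostatin of a class of inhibitory interneurons (chromosome 16, 23889573 to 23890958), was at 620.7 ± 42.2 CPM (n = 3) against 65.3 ± 30.4 CPM (n = 3), a log2 fold change of 3.25 ± 0.33 (edgeR adjusted p = 7.16e-05). Rspo1, a secreted activator of Wnt signalling and a marker of layer 4 (chromosome 4, 124986430 to 125009099), was at 83.5 ± 8.56 against 8.61 ± 0.893 CPM. Cartpt, a neuropeptide precursor (chromosome 13, 99898489 to 99901091), was at 35.5 ± 10.8 against 2.30 ± 2.11 CPM, and Cabp1, a neuronal calcium-binding protein, at 703.8 ± 24.8 against 84.8 ± 55.0 CPM. In the other direction, Gfap, the intermediate filament of astrocytes, was at 160.9 ± 20.1 against 6790 ± 1710 CPM, a log2 fold change of -5.40 ± 0.25 (edgeR adjusted p = 1.72e-06).

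Of 13 excitatory neuron markers, 12 were higher in libraries labelled Il17rb-Cre than in those labelled Il17ra-Cre and 0 lower (13 higher when adjusted over the list alone; median log2 fold change 2.17, camera adjusted p = 2.23e-07). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was at 1892 ± 420.2 against 341.8 ± 245.6 CPM. In Il17ra-Cre replicates 1 to 3 it was at 166.6, 236.1 and 622.5 CPM. Nrgn, another member, was at 1160, 1250 and 5504 CPM there, against a mean of 15740 CPM in Il17rb-Cre. The difference in both genes was thus smallest against replicate 3. Of 22 genes of synaptic vesicle release 18 were higher and 0 lower, the same counts as adjusted over the list alone (median 1.72, camera adjusted p = 1.61e-09). Snap25, a membrane fusion protein of the synapse, was at 10340 ± 220.8 against 2061 ± 1148 CPM. The pan-neuronal list had 9 of 12 members higher and 1 lower, also adjusted over the list alone, at a median of 1.67 (camera adjusted p = 5.89e-05). None of these calls held when the correlation between list members was estimated. The adjusted p with an estimated correlation was 0.278 for the excitatory and pan-neuronal lists and 0.296 for vesicle release.

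Channel and receptor genes moved the same way in libraries labelled Il17rb-Cre. Of 30 potassium channel genes 21 were higher and 2 lower than in Il17ra-Cre (22 and 2 adjusted over the list alone; median 1.26, camera adjusted p = 9.11e-06). Kcnh3 rose by 2.37 ± 0.34 on the log2 scale, while Kcnj10, the inward rectifier of astrocytes, fell by 5.28 ± 0.37. Of 26 sodium, calcium and HCN channel genes 15 were higher and 0 lower (17 and 1 adjusted over the list alone; median 1.42, camera adjusted p = 3.61e-06). Of 12 GABA-A receptor subunits 9 were higher and 1 lower (9 and 1 adjusted over the list alone; median 1.66, camera adjusted p = 5.42e-05). Of 17 ionotropic glutamate receptor subunits 9 were higher and 1 lower (12 and 2 adjusted over the list alone; median 1.08, camera adjusted p = 0.00592). Of 38 neuromodulator receptors 20 were higher and 0 lower (21 and 0 adjusted over the list alone; median 1.62, camera adjusted p = 3.95e-06). Among them were the muscarinic receptor Chrm1 with a log2 fold change of 2.58 ± 0.31 and the neuropeptide Y receptor Npy1r with 2.44 ± 0.29. Of 18 neuropeptides 10 were higher and 1 lower (12 and 1 adjusted over the list alone; median 1.48, camera adjusted p = 1.91e-04). Of 17 immediate early genes, which respond to neuronal activity, 8 were higher and 1 lower, also adjusted over the list alone (median 1.05, camera adjusted p = 0.00919). Egr3 rose by 2.13 ± 0.25 and Jun fell by 1.94 ± 0.33. Without Il17ra-Cre replicates 1 and 2, left out after the data were seen, the immediate early median was 0.25, with 1 Il17ra-Cre library left. For these 7 lists the adjusted p with an estimated correlation was between 0.296 and 0.569.

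Among markers of neuronal types, the Pvalb and Sst interneuron list had 9 of 12 members higher and 1 lower than in Il17ra-Cre, also adjusted over the list alone (median 1.83, camera adjusted p = 0.00199). Satb1 rose by 1.97 ± 0.36 and Sox6 fell by 2.19 ± 0.20. The broader inhibitory neuron list was not called, with 4 of 12 higher and 2 lower (6 and 2 adjusted over the list alone; median 0.94, camera adjusted p = 0.112). The layer 2/3 list had 6 of 12 higher and 2 lower (8 and 2 adjusted over the list alone; median 1.14, camera adjusted p = 0.0051). Lamp5 was at 500.7 ± 26.1 against 81.1 ± 18.2 CPM, and Wfs1 fell by 1.97 ± 0.26. The layer 4 list had 3 of 7 higher and 0 lower, also adjusted over the list alone (median 0.66, camera adjusted p = 0.00919). The layer 6 corticothalamic list had 4 of 10 higher and 0 lower (5 and 0 adjusted over the list alone; median 1.48, camera adjusted p = 0.00635). Not called, with the same counts adjusted over the list alone, were layer 5 extratelencephalic (3 of 12 higher, 1 lower; camera adjusted p = 0.112) and layer 5 intratelencephalic markers (1 of 6 higher, 1 lower; 0.256). Nor were layer 5/6 near-projecting (0 of 6 higher, 1 lower; camera adjusted p = 0.456) and layer 6 intratelencephalic markers (1 of 6 higher, 1 lower; 0.629). Axon guidance genes went both ways, 15 of 36 higher and 5 lower (16 and 5 adjusted over the list alone; median 0.79, camera adjusted p = 0.0212; 0.0745 without Il17ra-Cre replicate 3). Ephb6 was at 1.95 and, on the lower side, the ligands Efnb3 at -4.01 and Sema6d at -3.12. The adjusted p of these 5 lists was between 0.278 and 0.457 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 15 of 101 members higher and 4 lower (2 and 4 adjusted over the list alone; median 0.48, camera adjusted p = 0.00156, and adjusted p = 0.653 with an estimated correlation). The lower members were Cox7a1, Cox6b2, Cox4i2 and Ndufa4l2, which encode tissue-restricted subunits or their relatives. The cytosolic ribosomal protein list was called at a median of 0.19 with 2 of 83 members higher and 3 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.0484, and adjusted p = 0.761 with an estimated correlation). Without Il17ra-Cre replicates 1 and 2, left out after the data were seen, its direction turned (median -0.38), with 1 Il17ra-Cre library left. That call was lost without Il17ra-Cre replicate 1 or 2 (camera adjusted p = 0.13 and 0.416), Il17rb-Cre replicate 1 (0.313) or Il17rc-Cre replicate 2, 3 or 4 (0.0528, 0.0504 and 0.0571). Without both of Il17ra-Cre replicates 1 and 2 the layer 4 and oxidative phosphorylation medians were 0.28 and 0.083.

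Glial and mural markers were lower in libraries labelled Il17rb-Cre than in those labelled Il17ra-Cre. Of 14 astrocyte markers 13 were lower and 0 higher (median -3.56, camera adjusted p = 1.59e-16). Aqp4, the water channel of astrocyte endfeet, had a log2 fold change of -5.43 ± 0.36 and the transcription factor Sox9 one of -4.25 ± 0.25. All 13 oligodendrocyte markers were lower (median -4.59, camera adjusted p = 3.93e-05), with the myelin glycoprotein gene Mag at 41.5 ± 4.21 against 1545 ± 1001 CPM. The most abundant members were uneven over Il17ra-Cre replicates 1 to 3, so the size of their folds leans on replicates 1 and 2. Mbp was at 21980, 14210 and 2014 CPM there and Cnp at 7562, 5611 and 1021 CPM, against means of 526.9 and 174.4 CPM in Il17rb-Cre. Of 8 markers of oligodendrocyte precursors 7 were lower (median -3.52, camera adjusted p = 1.91e-04), and of 16 markers of microglia and macrophages 15 (median -5.07, camera adjusted p = 2.96e-05). The counts for these 4 lists were the same when adjusted over the list alone. Itgam, Mrc1 and Ptprc had no count in any library labelled Il17rb-Cre; with these 3 genes set at a floor of 3 counts over the group, the microglial median was -4.81. Mural and fibroblast-like markers had 9 of 14 members lower and 0 higher (12 and 0 adjusted over the list alone; median -4.04, camera adjusted p = 1.91e-04). For these 5 lists the adjusted p was between 0.278 and 0.416 with an estimated correlation. Endothelial markers were not called: 4 of 12 were lower, also adjusted over the list alone (camera adjusted p = 0.0776).

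Immune genes were lower in libraries labelled Il17rb-Cre as well. Of 19 genes of the interferon response and antigen presentation, 18 were lower than in Il17ra-Cre, also adjusted over the list alone (median -3.48, camera adjusted p = 9.02e-15). The interferon-induced Ifit3 was at 82.1 ± 22.6 against 2190 ± 871.4 CPM. Of 18 members of the IL-17 signalling list 16 were lower (17 adjusted over the list alone; median -1.88, camera adjusted p = 3.95e-06). Cebpd, a transcription factor downstream of IL-17 receptors, had a log2 fold change of -5.34 ± 0.37, and Nfkbia, an inhibitor of NF-kappaB, one of -3.55 ± 0.41. Of 22 cytokine receptors 18 were lower (21 adjusted over the list alone; median -2.20, camera adjusted p = 1.02e-05), with the tumour necrosis factor receptor Tnfrsf1a at -5.52 ± 0.47. Their adjusted p was 0.278 or 0.296 with an estimated correlation. The genes lowest by fold included Ubd, an interferon-inducible ubiquitin-like protein, at 0.0801 ± 0.0848 against 230.4 ± 147.4 CPM, and the class II antigen presentation gene H2-Ab1 at 2.32 ± 1.27 against 1202 ± 615.7 CPM. Ubd had only 14 reads over the 3 Il17rb-Cre libraries, and H2 and Gbp family members can share reads with near-identical copies, so their folds are uncertain.

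In this comparison 8268 of 20301 tested genes differed, 3321 higher and 4947 lower in libraries labelled Il17rb-Cre (edgeR). Of these, 625 were more than 4-fold higher and 3007 more than 4-fold lower. Without both of Il17ra-Cre replicates 1 and 2, whose Rpl10a level was low, 1 Il17ra-Cre library is left. The number of genes in that fit therefore cannot show whether the difference holds without them.

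**Figure D2:**
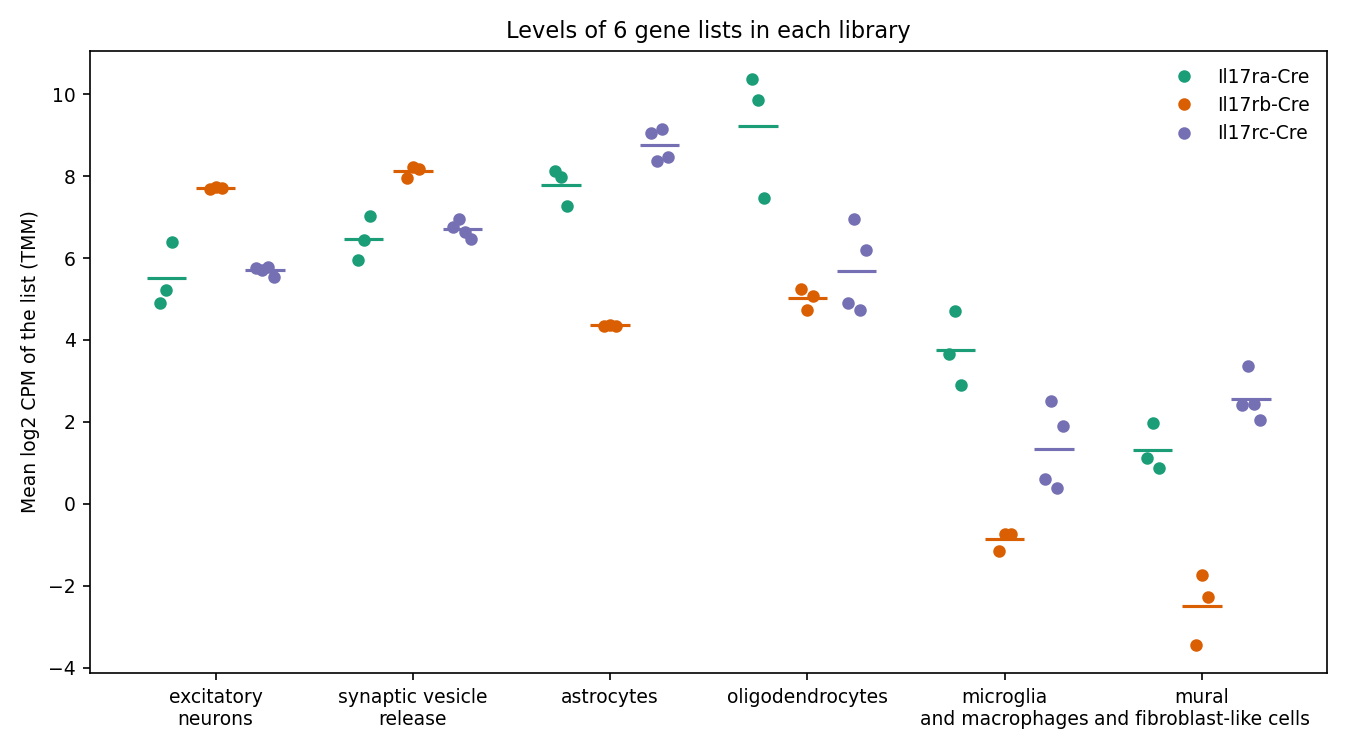
Mean log2 CPM (TMM-scaled) of the members of 6 gene lists, with 1 point per library and a bar at the group mean, for libraries labelled Il17ra-Cre (3), Il17rb-Cre (3) and Il17rc-Cre (4). Astrocyte markers lie at 4.35 and 4.36 in the Il17rb-Cre libraries and between 7.27 and 9.16 in the others, and oligodendrocyte markers at 10.37, 9.87 and 7.46 in the Il17ra-Cre libraries.

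Against libraries labelled Il17rc-Cre, those labelled Il17rb-Cre had higher excitatory and pan-neuronal markers and lower astrocyte markers, while inhibitory neuron markers were not called. The called lists had an adjusted p between 0.189 and 0.414 with an estimated correlation. Nrgn, a calmodulin-binding protein of excitatory neurons, was at 15740 ± 2109 CPM (n = 3) against 2120 ± 688.9 CPM (n = 4), a log2 fold change of 2.89 ± 0.52 (edgeR adjusted p = 0.00171). The activity-regulated gene Arc was at 1476 ± 555.3 against 220.4 ± 114.1 CPM (log2 fold change 2.74 ± 0.41, edgeR adjusted p = 5.5e-04), and Rspo1 had a log2 fold change of 2.87 ± 0.19 (edgeR adjusted p = 4.72e-06). Ptx3, a secreted pattern recognition protein, had a log2 fold change of -8.84 ± 0.68 (edgeR adjusted p = 1.05e-05), on 15 reads in the Il17rb-Cre libraries, and Gfap one of -5.36 ± 0.25 (edgeR adjusted p = 7.69e-07). Other genes among those largest by fold were Cartpt, Ramp3, Gng13 and Adamtsl2 on the higher side and the pericyte receptor gene Pdgfrb on the lower side. More than 50% of the exonic length of Gng13 is shared with Chtf18, which leaves its value uncertain.

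All 13 excitatory neuron markers were higher in libraries labelled Il17rb-Cre than in those labelled Il17rc-Cre (median log2 fold change 1.96, camera adjusted p = 5.26e-07). Camk2a, a kinase of excitatory synapses, was at 563.3 ± 26.8 against 174.6 ± 48.0 CPM. The pan-neuronal list had 10 of 12 members higher (median 1.59, camera adjusted p = 1.08e-05) and synaptic vesicle release 18 of 22 (median 1.60, camera adjusted p = 5.46e-08), and none of these 3 lists had a lower member. Their counts were the same when adjusted over the list alone. Potassium channels had 20 of 30 higher and 2 lower (21 and 2 adjusted over the list alone; camera adjusted p = 1.42e-04). Sodium, calcium and HCN channels had 14 of 26 higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 1.11e-05). Immediate early genes had 9 of 17 higher and 2 lower (10 and 2 adjusted over the list alone; median 1.62, camera adjusted p = 0.00188). For these 6 lists the adjusted p with an estimated correlation was between 0.368 and 0.54.

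Ionotropic glutamate receptors (9 of 17 higher, 1 lower; camera adjusted p = 0.0131), GABA-A receptors (8 of 12 higher, 1 lower; camera adjusted p = 0.00999), neuromodulator receptors (16 of 38 higher, 2 lower; camera adjusted p = 6.17e-04) and neuropeptides (9 of 18 higher, 2 lower; camera adjusted p = 0.00999) were called higher in libraries labelled Il17rb-Cre. Adjusted over the list alone the counts were 9 and 1, 8 and 2, 18 and 2, and 9 and 2. The gastrin-releasing peptide gene Grp rose by 3.38 ± 0.48 on the log2 scale, Sst was at 620.7 ± 42.2 against 154.9 ± 31.8 CPM, and the glutamate receptor subunit Grin2c fell by 5.00 ± 0.95. Axon guidance genes (14 of 36 higher, 3 lower; 15 and 3 adjusted over the list alone; camera adjusted p = 0.0211), layer 2/3 markers (6 of 12 higher, 3 lower, also adjusted over the list alone; camera adjusted p = 0.0275) and layer 6 corticothalamic markers (3 of 10 higher, 0 lower, also adjusted over the list alone; camera adjusted p = 0.0435) passed by less. The corticothalamic call was lost without Il17rb-Cre replicate 2 (camera adjusted p = 0.0791) and without Il17rc-Cre replicate 1, 2 or 3 (camera adjusted p = 0.0537, 0.0683 and 0.0514). The adjusted p of these 7 lists was 0.54 or 0.567 with an estimated correlation. The layer 2/3 call was lost without Il17ra-Cre replicates 1 and 2 (camera adjusted p = 0.0735). The axon guidance, corticothalamic and ribosomal protein calls were lost without Il17rc-Cre replicates 1 and 3 (0.0671, 0.073 and 0.0924). Not called were inhibitory neurons (1 of 12 higher, 3 lower, also adjusted over the list alone; median -0.41, camera adjusted p = 0.527) and layer 4 (2 of 7 higher, 1 lower, also adjusted over the list alone; camera adjusted p = 0.204). The layer 5 extratelencephalic, layer 5 intratelencephalic, layer 5/6 near-projecting and layer 6 intratelencephalic lists were not called either (camera adjusted p = 0.159, 0.43, 0.527 and 0.527). Nor were Pvalb and Sst interneurons, with 7 of 12 higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0936). The cytosolic ribosomal protein list was called with 6 of 83 members higher and 2 lower (1 and 1 adjusted over the list alone; median 0.31, camera adjusted p = 0.0275, and adjusted p = 0.778 with an estimated correlation). The call was lost without Il17rb-Cre replicate 1 (camera adjusted p = 0.294) and without Il17rc-Cre replicate 1 (camera adjusted p = 0.0619).

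All 14 astrocyte markers were lower in libraries labelled Il17rb-Cre than in those labelled Il17rc-Cre, also adjusted over the list alone (median -5.02, camera adjusted p = 3.39e-24, and adjusted p = 0.189 with an estimated correlation). Fgfr3, a growth factor receptor of astrocytes, was at 6.40 ± 1.68 against 336.1 ± 65.9 CPM, although 13.9% of its exonic length overlaps another gene. Mural and fibroblast-like markers had 12 of 14 members lower, also adjusted over the list alone (median -4.60, camera adjusted p = 2.8e-06). Vitronectin, Vtn, was at 2.27 ± 0.471 against 356.4 ± 162.4 CPM. Endothelial markers had 7 of 12 lower (9 adjusted over the list alone; median -3.17, camera adjusted p = 0.00964). Oligodendrocyte precursors had 6 of 8 lower, also adjusted over the list alone (median -3.42, camera adjusted p = 0.00257). With an estimated correlation the adjusted p of these 3 lists was between 0.368 and 0.54. Markers of mature oligodendrocytes were not called: 1 of 13 was lower (0 adjusted over the list alone; median -0.75, camera adjusted p = 0.527). The microglial list had 10 of 16 members lower (13 adjusted over the list alone), and its median of -2.38, which did not move with the 3 genes without counts at their floor, missed the threshold as a list (camera adjusted p = 0.0536).

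All 19 interferon response and antigen presentation genes were lower, also adjusted over the list alone (median -3.36, camera adjusted p = 7.55e-13). Lower too were 15 of 18 IL-17 signalling genes (16 adjusted over the list alone; median -1.47, camera adjusted p = 6.82e-06) and 15 of 22 cytokine receptors, also adjusted over the list alone (median -2.04, camera adjusted p = 5.32e-05). Ifit3 fell by 4.60 ± 0.42 on the log2 scale, Cebpd by 5.23 ± 0.36 and the interleukin-1 receptor gene Il1r1 by 3.69 ± 0.33. Cholesterol synthesis genes were lower in libraries labelled Il17rb-Cre, 14 of 18 with 0 higher, also adjusted over the list alone (camera adjusted p = 2.56e-04). Among them were lanosterol synthase, Lss, at -2.02 ± 0.23 and Nsdhl at -1.49 ± 0.15. For these 4 lists the adjusted p with an estimated correlation was between 0.368 and 0.44. In this comparison 8057 genes differed, 3603 higher and 4454 lower in libraries labelled Il17rb-Cre (edgeR), with 406 more than 4-fold higher and 2780 more than 4-fold lower.

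Of the lists called between libraries labelled Il17ra-Cre and those labelled Il17rc-Cre, 5 were higher and 11 lower in Il17ra-Cre, and 0 were called with an estimated correlation. Oligodendrocyte markers (11 of 13) and microglial markers (7 of 16) had the most members past the test, and the lists called lower had at most 4 (adjusted p = 0.24 with an estimated correlation for both of the named lists). Mbp, myelin basic protein, was at 12730 ± 10060 CPM (n = 3) against 743.9 ± 577.9 CPM (n = 4), a log2 fold change of 4.10 ± 0.77 (edgeR adjusted p = 0.0384). The lysozyme gene Lyz2 was at 261.7 ± 239.1 against 6.37 ± 5.07 CPM (log2 fold change 5.36 ± 0.97, edgeR adjusted p = 0.0383) and the lipocalin gene Apod at 10250 ± 6566 against 522.5 ± 512.8 CPM (edgeR adjusted p = 0.0445). Higd1b, a pericyte marker, was at 13.2 ± 4.61 against 84.7 ± 26.7 CPM (log2 fold change -2.68 ± 0.33, edgeR adjusted p = 0.0154), and the adenosine receptor gene Adora2a at 3.40 ± 1.37 against 34.7 ± 27.7 CPM. Each of these calls was lost without Il17ra-Cre replicate 1 or 2 or Il17rc-Cre replicate 1 or 3. The spread within both groups was wide: Mbp was at 21980, 14210 and 2014 CPM in the 3 Il17ra-Cre replicates.

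Of 13 oligodendrocyte markers 11 were higher in libraries labelled Il17ra-Cre (13 adjusted over the list alone; median log2 fold change 3.69, camera adjusted p = 9.32e-22). The myelin gene Mog was at 3.89 ± 0.68. Of 16 microglial markers 7 were higher (9 adjusted over the list alone; median 2.28, camera adjusted p = 1.68e-11). The lipid receptor Trem2 and the complement gene C1qc were at 3.65 ± 0.46 and 3.56 ± 0.65. With an estimated correlation the adjusted p was 0.24 for both lists. Lists called higher with no member past the test over all genes were hippocampal neurons (3 of 7 higher adjusted over the list alone; median 1.15, camera adjusted p = 0.0375) and the interferon list (0 of 19 adjusted over the list alone; median 0.59, camera adjusted p = 0.0375). The third was the unfolded protein and heat shock list (5 of 14 higher adjusted over the list alone; median 0.43, camera adjusted p = 0.00157). With an estimated correlation their adjusted p was 0.24, 0.816 and 0.478. Without Il17ra-Cre replicates 1 and 2, which leaves 1 Il17ra-Cre library, the interferon list changed direction in camera, at a median of 0.046. Its call was lost without Il17ra-Cre replicate 1 (camera adjusted p = 0.516) or Il17rc-Cre replicate 1, 2 or 3 (0.157, 0.071 and 0.0675). The hippocampal call was lost without Il17rc-Cre replicate 2 or 4 (camera adjusted p = 0.0991 and 0.0721). Its most abundant members were uneven in Il17ra-Cre replicates 1 to 3, Zbtb20 at 205.0, 188.2 and 91.5 CPM and Prox1 at 99.7, 80.8 and 10.5 CPM. In Il17rc-Cre they averaged 99.5 and 5.49 CPM. Prox1 is also on the Vip, Lamp5 and Sncg interneuron list, so the call does not single out hippocampal neurons. Without Il17rc-Cre replicates 1 and 3, also left out after the data were seen, the interferon and the unfolded protein and heat shock calls were lost (camera adjusted p = 0.711 and 0.0844).

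Astrocyte markers had 2 of 14 members lower in libraries labelled Il17ra-Cre than in Il17rc-Cre (7 adjusted over the list alone; median -0.85, camera adjusted p = 1.75e-09). Fgfr3 was at 88.7 ± 15.4 against 336.1 ± 65.9 CPM. Inhibitory neuron markers had 3 of 12 lower (10 adjusted over the list alone; median -1.30, camera adjusted p = 3.21e-08), the GABA synthesis gene Gad2 by -1.09 ± 0.19. Striatal projection neuron markers had 2 of 8 lower (6 adjusted over the list alone; median -2.16, camera adjusted p = 8.32e-07), among them Adora2a. Replicates were uneven: the list averaged 2.07, 2.42 and 4.35 log2 CPM in the Il17ra-Cre replicates and 5.85, 3.39, 6.93 and 5.51 in the Il17rc-Cre replicates. Penk, the enkephalin precursor, was at 207.1 CPM in Il17ra-Cre replicate 3 and at 31.1 CPM in Il17rc-Cre replicate 2. Mural markers had 2 of 14 lower, Rgs5 and Vtn (4 adjusted over the list alone; median -1.04, camera adjusted p = 9.64e-05). Cholesterol synthesis had 4 of 18 lower (11 adjusted over the list alone; median -0.78, camera adjusted p = 7.85e-11), Sqle, Fdft1, Mvd and Nsdhl, by between -0.66 and -1.12. With an estimated correlation the adjusted p of these 5 lists was between 0.223 and 0.357. Also called lower were Pvalb and Sst interneurons (0 of 12 past the test, 2 lower adjusted over the list alone; median -0.68, camera adjusted p = 7.47e-04), and layer 4 (0 of 7, 2 adjusted over the list alone; median -0.81, camera adjusted p = 0.00267). So were GABA-A receptors (0 of 12, 1 adjusted over the list alone; median -0.37, camera adjusted p = 6.66e-04), and neuromodulator receptors (0 of 38, 0 adjusted over the list alone; median -0.36, camera adjusted p = 0.00292). The last of these lists were neuropeptides (0 of 18, 1 adjusted over the list alone; median -0.64, camera adjusted p = 0.0101) and nuclear oxidative phosphorylation genes (1 of 101, 1 adjusted over the list alone; median -0.13, camera adjusted p = 0.00121). With an estimated correlation their adjusted p was between 0.24 and 0.862. Without Il17ra-Cre replicates 1 and 2, which leaves 1 Il17ra-Cre library, camera's direction turned for the last 3. In that fit the median turned only for oxidative phosphorylation (0.19) and stayed at -0.12 for neuromodulator receptors and -0.24 for neuropeptides. The layer 4 and GABA-A receptor medians were -0.33 and -0.26 there. Without Il17rc-Cre replicates 1 and 3, layer 4 and oxidative phosphorylation were not called (camera adjusted p = 0.0617 and 0.488). The neuromodulator receptor and neuropeptide calls were lost without Il17ra-Cre replicate 1 (camera adjusted p = 0.115 and 0.197), and the oxidative phosphorylation call without Il17ra-Cre replicate 2 (0.244). Excitatory neuron markers were not called (median -0.02, camera adjusted p = 0.402).

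In this comparison 443 genes differed, 281 higher and 162 lower in libraries labelled Il17ra-Cre (edgeR), and 216 higher and 226 lower with DESeq2 size factors. A fit of only the 2 groups compared called 1 gene, not among the 443 (3201 at an unadjusted p under 0.05), and none of the genes named singly. The count rested on single libraries: edgeR called 0 genes without Il17ra-Cre replicate 1 or 2 or without Il17rc-Cre replicate 3 (2827, 2930 and 2856 at an unadjusted p under 0.05). It called 4 without Il17rc-Cre replicate 1, 37 without Il17rc-Cre replicate 4, 37, 15 and 43 without Il17rb-Cre replicate 1, 2 or 3, and 2886 without Il17ra-Cre replicate 3. On all libraries DESeq2 called 2101 and limma voom with quality weights 4579. Those weights were 0.126 for Il17ra-Cre replicate 3 and between 0.514 and 2.73 for the other libraries, so replicate 3 counted little there.

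Over all 3 groups 8843 genes differed (edgeR). Libraries labelled Il17rb-Cre had 2645 genes higher than in both other groups, among them Rspo1, Cartpt, Sst, Snap25 and Igfbp6, an insulin-like growth factor binding protein at 454.6 CPM against 70.9 and 75.9 CPM in Il17ra-Cre and Il17rc-Cre. Libraries labelled Il17ra-Cre had 180 such genes, led by Lyz2, Hk3, Hapln2, Car14, Apod and Mbp, and libraries labelled Il17rc-Cre had 128, led by Adora2a, Tmem204, Heyl, Tlcd1, Higd1b and Ndufa4l2. Overlap of independent lists would give 589.4, 68.5 and 35.5 genes, and 20 simulated datasets of unchanged groups, which show chance with no effect, gave 0 in each case. The simulation leaves out real effects and the overlap of independent lists leaves out the shared libraries, so neither is the value to expect where both comparisons hold effects. When the Il17rc-Cre libraries were split so that each comparison had 2 of its own, 5 of 6 splits called 0 genes against Il17ra-Cre and so say nothing of the overlap. In the split with replicates 1 and 3 against Il17ra-Cre, 72 of 86 called genes were also higher than in Il17rb-Cre. Groups of 3 could not be split in this way, so part of the Il17ra-Cre and Il17rb-Cre counts may come from the shared libraries. The Il17ra-Cre and Il17rc-Cre counts fell to 0 without Il17ra-Cre replicate 1 or 2 or Il17rc-Cre replicate 3, and to 0 and 2 without Il17rc-Cre replicate 1. They fell to between 2 and 28 without any 1 Il17rb-Cre library or Il17rc-Cre replicate 4, and without Il17ra-Cre replicate 3 they were 1231 and 400. The Il17rb-Cre count was 1693 and 1746 without its own replicates 2 and 3.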

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

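The chance tests were planned before the results were seen, and the tests of the 3 patterns weighed here were chosen only afterwards. When the libraries were regrouped in every possible way, the 8268 genes of Il17rb-Cre against Il17ra-Cre came from 1 of 10 groupings, with 0 genes in the largest other; 10 groupings are too few to judge. For Il17rb-Cre against Il17rc-Cre only 1 of 35 groupings reached the real number, with at most 1 gene in any other, and for Il17ra-Cre against Il17rc-Cre 1 of 35, with 290 in the grouping that puts Il17rc-Cre replicate 2 in place of Il17ra-Cre replicate 3. Gene lists were less specific: 2 of 10, 9 of 35 and 13 of 35 groupings gave as many called lists, with up to 27, 27 and 24 lists in the others. Chance therefore cannot be excluded for the number of lists in Il17rb-Cre against Il17rc-Cre and Il17ra-Cre against Il17rc-Cre, and for Il17rb-Cre against Il17ra-Cre there are too few groupings. Among 100 regroupings into 3, the genes differing over all groups were reached by 1 (largest other 6938), the genes higher in Il17ra-Cre by 2 (largest other 2411), in Il17rb-Cre by 1 (largest other 0) and in Il17rc-Cre by 2 (largest other 1061). The large other values keep the 3 Il17rb-Cre libraries together under another name, so they show structure of the samples.

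Il17ra-Cre replicate 3 stood apart from replicates 1 and 2, with Mbp at 2014 CPM against 21980 and 14210 CPM. A candidate explanation is that it mixes RNA like theirs with RNA like that of the Il17rb-Cre libraries, but the share needed was 0.425 higher for astrocyte than for oligodendrocyte markers, which argues against a single mixture. A wrong label remains open: its highest rank correlation with an Il17rc-Cre library was 0.9616, above the 0.9461 with another Il17ra-Cre library. Its Rpl10a of 678.8 CPM, however, lay outside the Il17rc-Cre range. Less construct RNA in replicates 1 and 2 also remains open, where Rpl10a relative to the other ribosomal protein genes was at most -0.5144 on the log2 scale. Of the other 8 libraries, however, Il17rc-Cre replicates 2 and 4 were only 0.58 and 0.64 above that median, less than the 1 predicted.

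In libraries labelled Il17rb-Cre excitatory markers were higher and astrocyte markers lower than in both other groups. A difference in scaling could move both lists only the same way, whereas their medians against Il17ra-Cre lay 5.739 apart on the log2 scale. A single pool of background RNA of the same make-up in the other groups is also unlikely, because oligodendrocyte and astrocyte medians differed by 4.538 between Il17ra-Cre and Il17rc-Cre. That gap leans on Il17ra-Cre replicates 1 and 2, where Rpl10a was lowest: Mbp was at 21980 and 14210 CPM there against 2014 CPM in replicate 3. Background that differs in make-up between libraries was not tested. That the drivers mark different cells is a hypothesis that was not tested, since no whole-tissue RNA was analysed here.

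Il17ra and Il17rb were not higher in the libraries labelled with their own driver, and Il17rc was level between Il17rc-Cre and Il17ra-Cre. Swapped labels between Il17ra-Cre and Il17rb-Cre could account for the Il17rb value of -1.664 and the Il17ra value of 0.51 ± 0.24 for Il17rb-Cre against Il17ra-Cre. Neither passed the test on all libraries, though Il17ra did without Il17rb-Cre replicate 1 (edgeR adjusted p = 0.0263). Il17rb did without Il17rc-Cre replicates 1 and 3, left out after the data were seen (edgeR adjusted p = 0.0423). A swap therefore stays open. Loss of the transcript through the Cre insertion in every line would make each receptor lower in its own line than in both others. For Il17rc this was not met: the log2 fold change for Il17rb-Cre against Il17rc-Cre was -3.90 ± 0.46, so Il17rc was higher in its own line. Such a loss might still hide a difference from Il17ra-Cre. The Il17rc value of 0.05625 between Il17ra-Cre and Il17rc-Cre, which turned to -0.0194 with DESeq2 and -0.268 without Il17ra-Cre replicate 3, leaves that open.

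Of 245 values tested in the 4 Il17rc-Cre libraries, 8 had 1 library far from the other 3, where about 12.2 would be expected by chance; the gap to the nearest library is given as a share of the range. Tmem204 was at 2.346 log2 CPM in replicate 4 (gap 0.9196) against 4.349 to 4.524. Cspg4 was at 6.595 log2 CPM in replicate 2 (gap 0.9186) against 4.545 to 4.712. Ionotropic glutamate receptors averaged 3.249 in replicate 4 (gap 0.898) against 3.615 to 3.656. Layer 5 extratelencephalic markers averaged 3.297 in replicate 4 (gap 0.8975) against 3.765 to 3.819. Kcnh3 was at 5.227 in replicate 4 (gap 0.8959) against 6.097 to 6.198. Il1r1 was at 2.666 in replicate 1 (gap 0.873) against 2.999 to 3.048. Sodium, calcium and HCN channels averaged 3.363 in replicate 4 (gap 0.8337) against 3.95 to 4.067. Sqle was at 6.088 in replicate 4 (gap 0.8334) against 5.878 to 5.913.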

How the results depend on the processing

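The fits without Il17ra-Cre replicates 1 and 2, the fits without Il17rc-Cre replicates 1 and 3, and fry were chosen only after the results were seen. Leaving out Il17ra-Cre replicates 1 and 2 leaves 1 Il17ra-Cre library, so the spread within that group cannot be measured. The numbers of genes listed for that fit therefore cannot show whether a result holds without these replicates, and no conclusion is drawn from them. For the changes given here the cause was not tested. Genes differing for Il17ra-Cre against Il17rc-Cre numbered 443, and 2101 with DESeq2, 4579 with limma voom, 691 with the CPM filter, 1 with only the 2 groups and 0 without Il17rc-Cre replicates 1 and 3. Leaving out 1 library gave 0 to 2886. For Il17rb-Cre against Il17ra-Cre the range was 6541 to 9916, with 4192 without Il17ra-Cre replicates 1 and 2, for Il17rb-Cre against Il17rc-Cre 5946 to 9151, and over the 3 groups 6563 to 10758. Genes higher in Il17ra-Cre than in both others were 654 with DESeq2, 2179 with limma voom, 273 with the CPM filter, 0 to 1231 leaving out 1 library and 0 without Il17rc-Cre replicates 1 and 3. Those higher in Il17rb-Cre were 4126 with limma voom, 1693 to 3303 leaving out 1 library and 1336 without Il17ra-Cre replicates 1 and 2. Those higher in Il17rc-Cre were 670 with DESeq2, 825 with limma voom, 226 with the CPM filter, 0 to 400 leaving out 1 library and 0 without its replicates 1 and 3. Called lists were 0 in all comparisons with the estimated correlation. The rotation test fry called 34 for Il17rb-Cre against Il17rc-Cre and 8 for Il17ra-Cre against Il17rc-Cre. Of the camera calls, fry kept 23 of 25 for Il17rb-Cre against Il17ra-Cre and 21 of 22 for Il17rb-Cre against Il17rc-Cre. For Il17ra-Cre against Il17rc-Cre it kept 8 of 16. Leaving out 1 library gave 24 to 26, 21 to 23 and 15 to 24 lists for Il17rb-Cre against Il17ra-Cre, Il17rb-Cre against Il17rc-Cre and Il17ra-Cre against Il17rc-Cre. Upper quartile scaling moved the median log2 fold change of all genes from -0.0916 to 0.0408 for Il17rb-Cre against Il17ra-Cre and from 0.0227 to 0.127 for Il17rb-Cre against Il17rc-Cre.

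With replicate numbers as blocks, Il17ra-Cre against Il17rc-Cre gave 2 genes by title number and 1 by library number, genes higher in Il17ra-Cre 0 and 0, and those higher in Il17rc-Cre 2 and 1. Whether the numbers pair the samples stays undecided. Libraries of the same number correlated between -0.0826 and 0.181. By title number 2 of 9 such pairs were above 0.1, and by library number 1 of 9. Of 10 libraries, 5 correlated best with a library of their own title number and 3 with one of their own library number. With the blocks Il17ra turned to 0.0565 and 0.0356, Rpl10a to -0.526 and -0.456 and, by library number, Il17rd to 1.06, all for Il17ra-Cre against Il17rc-Cre.

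Leaving out 1 library moved values for Il17ra-Cre against Il17rc-Cre between -0.183 and 0.0600 for Il17ra, -0.268 and 0.267 for Il17rc and -1.88 and 0.582 for Rpl10a. Other values that changed sign there were Il17ra with limma voom (0.0864) and without Il17ra-Cre replicate 3 (0.0240), Il17rc-Cre replicate 3 (0.0348) or replicate 4 (0.0600). Rpl10a turned with limma voom (-1.71), which gave Il17ra-Cre replicate 3 a weight of 0.126, and without that replicate (-1.88). Il17rc turned with DESeq2 (-0.0194), DESeq2 size factors (-0.0190) and no filter (-0.00659). It also turned without Il17ra-Cre replicate 3 (-0.268), Il17rb-Cre replicate 1 (-0.00227), 2 (-0.00124) or 3 (-0.00139), Il17rc-Cre replicate 1 (-0.0749) or 3 (-0.00218), or both of these (-0.257), where Il17rd was at 1.73. Without Il17ra-Cre replicates 1 and 2, Pdia4 (-0.111) and Zbtb20 (-0.194) turned. In that fit camera's direction turned for the interferon (median 0.0464), neuromodulator receptor (-0.124), neuropeptide (-0.243) and nuclear oxidative phosphorylation (0.187) lists. For Il17rb-Cre against Il17ra-Cre that fit turned Rpl10a (-0.0591), Il17re (-0.732) and the ribosomal protein list (-0.380). Il17re also turned with limma voom (-0.0642) and without Il17ra-Cre replicate 1 (-0.496) or Il17rb-Cre replicate 1 (-1.002), the range leaving out 1 library being -1.002 to 0.783. For Il17rb-Cre against Il17rc-Cre, Il17rb turned with limma voom (0.980).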

Other observations

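The lists named here were among those fixed in advance; which of them to describe, and the genes uneven within a group, were chosen only after the results were seen. Mitochondrially encoded genes were not called as a list: 3 of 9 were lower in libraries labelled Il17rb-Cre than in Il17ra-Cre (median log2 fold change -0.93) and 2 of 9 lower than in Il17rc-Cre (median -1.11). Adjusted over the list alone 0 were lower in either comparison (camera adjusted p = 0.354 and 0.311). Of all 20301 tested genes, 4947 and 4454 were lower in these comparisons. Markers of layer 6b had 4 of 8 members lower than in Il17ra-Cre (2 higher and 4 lower adjusted over the list alone), and 1 higher and 2 lower than in Il17rc-Cre (1 and 3 adjusted over the list alone; median -1.11). That list was not called in either comparison (camera adjusted p = 0.456 and 0.468). Markers of Vip, Lamp5 and Sncg interneurons went both ways against Il17ra-Cre, 4 of 13 higher and 3 lower, and their median of 0.45 and mean of -0.08 differed in sign. Thalamic markers also differed in sign between median (0.70) and mean (-0.84) in that comparison.

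Within libraries labelled Il17rc-Cre, markers of striatal neurons were uneven. Penk, the enkephalin precursor, was at 194.1, 31.1, 485.8 and 209.7 CPM in replicates 1 to 4, and Ppp1r1b, a phosphatase regulator of striatal neurons, was highest in replicate 3 (835.1 CPM) as well. Aldoc, a glycolytic enzyme of astrocytes, was at 6745 and 6342 CPM in replicates 1 and 3 and at 1487 and 1861 CPM in replicates 2 and 4. Il25, the gene of the Il17rb ligand IL-17E, had at most 38 counts in a library and passed in none of the comparisons.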
